A study of Mus musculus with 6 samples.

How the data were processed

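Total RNA of samples labelled mouse skeletal muscle was sequenced in 6 libraries, 3 with titles naming them control and 3 with titles naming them FID. All 6 titles also carry the tag D3, and the sources used here do not spell out either abbreviation. Per the labels' protocols, mice received tamoxifen at 12 to 13 weeks of age for 5 days at 100 ug per g of body weight, with a pause of 1 week or more afterwards, and animals of both sexes were used. The series concerns a mouse model in which Igf1 is deleted in fibro-adipogenic progenitors (FAPs), the resident mesenchymal progenitor cells of muscle. Per the labels' protocols, libraries were made with a strand-specific kit from 1000 ng of RNA with integrity numbers above 5.6. The protocols describe RNA from tissue and RNA from primary FAPs, and every library has skeletal muscle as its source, so the labels leave open which of these the libraries hold. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, part of which may be technical. Sex-linked transcripts differed within each group, so neither group came from a single animal.

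The deposited values are raw counts of reads per gene, listed by Ensembl identifier. Per the submitters' processing notes, the build was mm10 and the tools included cutadapt, STAR, HTSeq, SAMtools, DESeq2 and Bowtie2 2.5.4, without a role or an order for each. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be separated. Reads that matched more than 1 place were set aside before counting, per the deposited count files, which lowers the counts of genes with near-identical copies. Each file holds 43432 genes, of which 42462 (97.8%) were matched to a symbol through a reference name table. Coordinates are those of the GENCODE annotation of the same mouse assembly. Entries that name no gene were left out of library sizes and tests. They made up between 9.60% and 10.9% of each file's total.

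Gene counts summed to 5201853, 9994541 and 10093757 in control 1, 2 and 3 and to 8750157, 9676812 and 9094185 in FID 1, 2 and 3. A count of 0 allows up to 3 counts, which corresponds to 0.593 CPM (counts scaled to a common library total) in control 1, the shallowest library, and to 0.293 CPM in control 3, the deepest. Such floors cover counting error only, since the reads carry no molecular identifiers. Libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom of 14.1 to 46.0 over genes with at least 20 counts, so no library was taken for a copy of another.

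Genes were filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which kept 12881 genes, and scaled with TMM factors. The comparison of FID with control used edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, with group as the only term. CPM values are TMM-normalised and are given as mean ± SD over 3 libraries. Log2 fold changes are FID over control with their standard errors (SE). These SE were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F. The interval given for Igf1 is built on such an SE and is approximate. The common biological coefficient of variation was 23.1%.

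There were 36 gene lists for cell types and processes of regenerating muscle, fixed before the data were examined. Of these, 30 had at least 5 tested members and were tested, the sex-linked list being left out by design. The test was camera of limma 3.58.1 on voom values with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry were run beside it. The estimates ranged from -0.098 for adipocytes to 0.94 for interferon response, with 0.58 for macrophages and 0.26 for extracellular matrix. Where the correlation within a list lies above the preset, camera with the preset gives p-values that are too small. Fry's direction p asks whether the genes of a list move, on balance, one way, and its mixed p whether they change in either direction. Members were also adjusted over the list alone. The score of a list in a library is the mean of log2(CPM + 1) over its members. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot give a p below 0.10.

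Genes named in the text follow a rule fixed before the data were examined. It takes Igf1, the strongest genes past the adjusted threshold, the 10 genes with the smallest unadjusted p where fewer than 10 pass, and up to 3 members with the smallest p from each list. This gives 115 genes beside Igf1, and which of them are printed was decided after their values were seen. Ifi202b, Hal, the sex markers and abundant marker genes that describe the content of the libraries were chosen after their values were seen.

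The test was checked on simulated counts for the comparison of FID with control, with 12881 genes, the means and depths of these libraries and 200 genes changed. EdgeR recovered 1.49% of genes changed 1.5-fold, 29.9% of those changed 2-fold and 92.4% of those changed 4-fold, and 9 of its 91 calls were unchanged genes. DESeq2 recovered 11.9%, 50.7% and 95.5% at the same folds, and 34 of its 139 calls were unchanged genes. Genes were simulated independently of each other, without differences between libraries that many genes share. The shares recovered therefore need not hold for the real libraries, and a count of 0 calls does not exclude 4-fold changes. In the real data, Mx1 (8.11-fold) and Ccl8 (4.19-fold) had edgeR adjusted p of 0.136 and 0.122.

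Alternatives fixed before the data were examined were other scaling factors, no filter and a stricter filter (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, each library left out in turn, Xist as a covariate, mitochondrial or myofibre genes left out, and the other list tests. Y-linked transcripts as a covariate and robust shrinkage in edgeR were added after seeing the data. Analyses ran in R 4.3.3 and figures in matplotlib 3.10.9. Counts per exon were not analysed here.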

Results

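RNA sequencing of samples labelled mouse skeletal muscle was deposited as counts per gene for 3 libraries labelled control and 3 labelled FID, all with the tag D3. The depth ranged from 5201853 to 10093757 gene counts per library, with control 1 the shallowest. Collagen transcripts were the most abundant on average over the libraries. Col1a1, a chain of type I collagen, averaged 16926 CPM, followed by Col1a2 at 14911 CPM and Col3a1 at 14353 CPM. Transcripts of mature myofibres were scarce although the labels give skeletal muscle as the source. Ckm, the muscle creatine kinase, stayed at or below 1.19 CPM in every library and Mb, myoglobin, at or below 1.56 CPM. Myh4, a myosin gene of adult fibres, stayed at or below 2.97 CPM and Acta1, the skeletal muscle actin gene, at or below 30.9 CPM. These values argue against RNA of whole muscle with its myofibres in any of the 6 libraries. Which cells the RNA came from, and how they were obtained, is not settled here. Lyz2, the lysozyme gene of myeloid cells, averaged 2297 CPM, and Cd3e, a T cell marker, had no count in any library.

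The series asks whether IGF-I made by FAPs is needed for their own function, and Igf1 is the gene the model deletes. Igf1 (ENSMUSG00000020053, mm10 chromosome 10, 87858265 to 87937042, plus strand, protein coding) stood at 134, 60.4 and 106 CPM in control 1, 2 and 3 and at 109, 107 and 81.6 CPM in FID 1, 2 and 3. The means were 100.2 ± 37.3 CPM in control and 99.2 ± 15.3 CPM in FID (SD, n = 3 each). The log2 fold change was -0.010 (SE 0.28, edgeR adjusted p 0.990), with a 95% interval of -0.67 to 0.65, so a fall of the whole-gene count by more than 37.0% lies outside that interval. Igf1 therefore does not check the labels, and the groups are called the libraries labelled control and FID throughout. Counts cover the whole gene, and a deletion of some exons would not have to lower them.

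Genes of the IGF system were lower together in the libraries labelled FID. All 17 tested members of the list, Igf1 included, had a log2 fold change below 0, and the list fell with a median of -0.60 (camera adjusted p 5.29e-04; adjusted p = 0.591 with an estimated correlation). Igfbp7, a secreted IGF-binding protein, measured 629 ± 142 CPM in control and 345 ± 80.7 CPM in FID. Igf1r, the receptor for IGF-I, measured 30.5 ± 5.38 against 20.1 ± 1.31 CPM. Irs1, an adaptor that carries the receptor's signal, measured 9.33 ± 3.92 against 4.05 ± 1.36 CPM. No member passed edgeR's test, with adjusted p of 0.143, 0.159 and 0.183 for these 3 genes. Without control 1 the median of the list was -0.31 (camera adjusted p 0.0340). In the same libraries, the medians of extracellular matrix genes, FAP markers and endothelial genes were -0.71, -0.42 and -0.60, and that of macrophage genes was 0.81.

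No single gene passed edgeR's adjusted test. The 10 genes with the smallest p separated the groups without overlap. Selection by p in the same comparison favours such separation, which 25.3% of all tested genes showed. Cd200r1, an inhibitory receptor of myeloid cells (chromosome 16, 44765736 to 44794978), measured 5.76 ± 0.21 CPM in control and 17.7 ± 0.573 CPM in FID, a 3.06-fold higher level (log2 fold change 1.61, SE 0.15). Clec11a, a secreted growth factor of bone and stroma (chromosome 7, 44302687 to 44306902), measured 68.9 ± 9.66 against 24.7 ± 2.21 CPM, 2.78-fold lower (log2 fold change -1.48, SE 0.15). Slc37a2, a sugar-phosphate transporter of macrophages (chromosome 9, 37227585 to 37255738), measured 74.0 ± 8.43 against 175 ± 18.2 CPM (log2 fold change 1.24, SE 0.14). The log2 fold changes of Alox5ap, needed for leukotriene synthesis, and of the RNA-editing enzyme gene Apobec1 were 0.98 (SE 0.12) and 1.47 (SE 0.19). Il7r, the interleukin-7 receptor, and Ccl8, a chemokine from a cluster of related genes, had 1.89 (SE 0.26) and 2.07 (SE 0.28), and the noncoding AI662270 had 1.20 (SE 0.15). Thsd7a and the cell-surface proteoglycan gene Gpc6 had -1.15 (SE 0.14) and -0.89 (SE 0.12). Adjusted p of these 10 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ranged from 0.109 to 0.122.

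**Figure D1:**
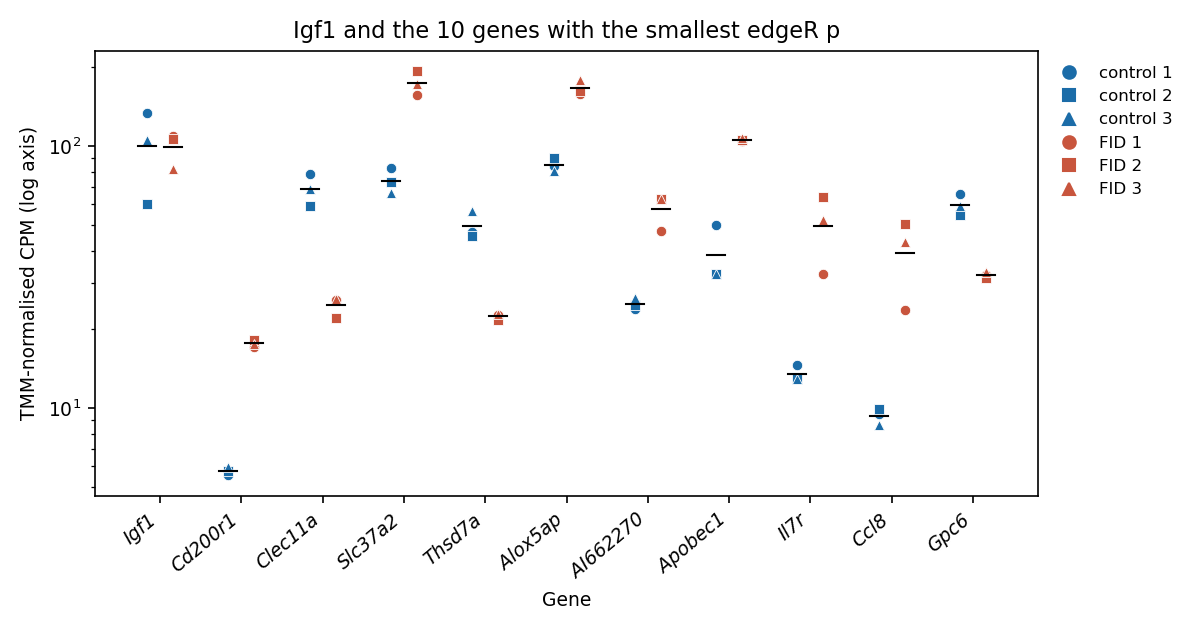
TMM-normalised CPM on a log axis for Igf1 and the 10 genes with the smallest edgeR p, with 1 point per library (blue control, red FID) and black bars for the group means. Igf1 overlapped between the groups, with means of 100.2 and 99.2 CPM, and the other 10 genes, selected by p in the same comparison, did not overlap.

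Of 12881 genes tested, 0 passed edgeR's adjusted threshold, and the smallest adjusted p was 0.109. An unadjusted p under 0.05 was reached by 2449 genes, 1263 higher and 1186 lower in FID, where 644 would be expected by chance. The 3 control and 3 FID libraries did not overlap in 3254 genes (25.3%), against 10% by chance. DESeq2 called 760 genes, 473 higher and 287 lower, limma-voom called 0, and limma-voom with sample weights called 1531. Without FID 1, edgeR called 359 genes, and without control 1 it called 3. On the first principal component (42.2% of variance) all FID libraries lay above all control libraries, with FID 1 at 2.05 and the other FID libraries at 41.0 and 38.5. The second component (31.6% of variance) spread the control libraries, with control 1 at 43.4 and control 3 at -38.6. The FID libraries lay between these, at -5.37 to 22.5.

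Genes of the extracellular matrix were lower in the libraries labelled FID. Of 29 tested members, 28 had a log2 fold change below 0, 18 passed when adjusted over the list alone and 0 passed over all genes, and the list fell with a median of -0.71 (camera adjusted p 4.91e-12; adjusted p = 0.398 with an estimated correlation). Col1a1 measured 21995 ± 1552 CPM in control and 11858 ± 2228 CPM in FID (log2 fold change -0.89, SE 0.18). Col12a1, a collagen found on fibril surfaces, and Col6a3, a chain of the filament-forming type VI collagen, had log2 fold changes of -1.46 (SE 0.22) and -0.78 (SE 0.16). Basement membrane genes fell with a median of -0.78, 13 of 16 passing when adjusted over the list alone (camera adjusted p 2.94e-09; adjusted p = 0.398 with an estimated correlation). Among them the laminin chains Lamb2 and Lama2 had -0.79 (SE 0.16) and -0.98 (SE 0.21), and Nid2, a laminin-binding nidogen, had -0.61 (SE 0.14).

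Related stromal lists were lower as well. FAP markers fell with a median of -0.42, with 19 of 21 members below 0 (camera adjusted p 5.04e-04; adjusted p = 0.398 with an estimated correlation). Mfap5, a microfibril protein, measured 144 ± 29.1 against 75.1 ± 18.7 CPM, Cxcl14 426 ± 37.1 against 304 ± 27.0 CPM, and the actin-severing Gsn 941 ± 9.92 against 640 ± 109 CPM. Ly6a, also in this list and its score, went the other way, with a log2 fold change of 1.61 (SE 0.51, edgeR adjusted p 0.179, DESeq2 adjusted p 0.0189). It stood at 434, 446 and 662 CPM in control 1, 2 and 3 and at 497, 2327 and 1890 CPM in FID 1, 2 and 3. Matrix proteases and their inhibitors fell with a median of -0.45 (camera adjusted p 0.00773; adjusted p = 0.398 with an estimated correlation), and Adamts12 had -0.87 (SE 0.16). The TGF-beta response list fell with a median of -0.50, or -0.33 without control 1 (camera adjusted p 0.00432; adjusted p = 0.434 with an estimated correlation). Ltbp3, which binds latent TGF-beta, had -1.11 (SE 0.26) and Inhba, which encodes an activin subunit, -1.06 (SE 0.28). Macrophage transcripts were higher in the same libraries, with list scores of 9.02 to 9.42 in FID against 7.70 to 8.58 in control.

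Macrophage genes were higher in the libraries labelled FID. All 23 tested members had a log2 fold change above 0 and 15 passed when adjusted over the list alone, and the list rose with a median of 0.81, or 1.76-fold (camera adjusted p 2.04e-12; adjusted p = 0.446 with an estimated correlation). Ctss, a lysosomal protease, measured 710 ± 239 CPM in control and 1935 ± 285 CPM in FID. Lgals3, a galectin abundant in macrophages, measured 484 ± 112 against 1205 ± 298 CPM, and the integrin gene Itgam 192 ± 8.65 against 317 ± 34.9 CPM. The list score was 8.58, 8.32 and 7.70 in control 1, 2 and 3 and 9.04, 9.42 and 9.02 in FID 1, 2 and 3.

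Lists that divide myeloid cells further did not pass. Inflammatory monocyte genes had a median of 0.11, with 10 members above and 10 below 0, and a mean of 0.41 (camera adjusted p 0.178). The median ranged from 0.055 without control 3 to 0.22 without FID 2, and the list scores of the groups did not overlap, with means of 5.72 in control and 6.11 in FID. Ccr2, a chemokine receptor of monocytes, measured 68.3 ± 19.2 against 173 ± 47.9 CPM, and F10, coagulation factor X, 8.38 ± 2.81 against 26.7 ± 8.66 CPM. Ly6c2, whose reads may be shared with a near-identical neighbour, measured 54.2, 713 and 552 CPM in FID 1, 2 and 3 against at most 33.8 CPM in control. Genes of resolving and resident macrophages had a median of 0.32 (camera adjusted p 0.0901), and 0.049 to 0.44 with 1 library left out, passing without control 2, FID 2 or FID 3 (camera adjusted p 0.00442, 0.00269 and 0.0274). In that list Folr2 had a log2 fold change of 1.26 (SE 0.25), Siglec1 1.90 (SE 0.46) and Gas6, a ligand for receptors of dying-cell uptake, -0.56 (SE 0.13). Neutrophil genes had a median of 0.31 (camera adjusted p 0.122), which ranged from -0.18 without control 1 to 0.56 without control 3 and was 0.41 without control 2, where the list passed (camera adjusted p 0.0420). Genes of dendritic cells and MHC class II had a median of -0.04 and a mean of 0.12 (camera adjusted p 0.195), and the median ranged from -0.42 without control 3 to 0.35 without control 1.

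Interferon response genes were higher in 2 of the 3 libraries labelled FID. All 24 members had a log2 fold change above 0 and 21 passed when adjusted over the list alone, but only 4 separated the groups without overlap. The list rose with a median of 2.08, or 4.24-fold (camera adjusted p 3.27e-10; adjusted p = 0.591 with an estimated correlation). Its score was 5.97, 4.50 and 5.50 in control 1, 2 and 3, 5.67 in FID 1, and 8.26 and 7.52 in FID 2 and 3. Mx1, an antiviral GTPase, measured 6.63 ± 1.86 against 54.2 ± 45.3 CPM. Oas3, a sensor of double-stranded RNA, and Ifit2, both from clusters of related genes, had log2 fold changes of 3.03 (SE 0.74) and 2.59 (SE 0.69).

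**Figure D2:**
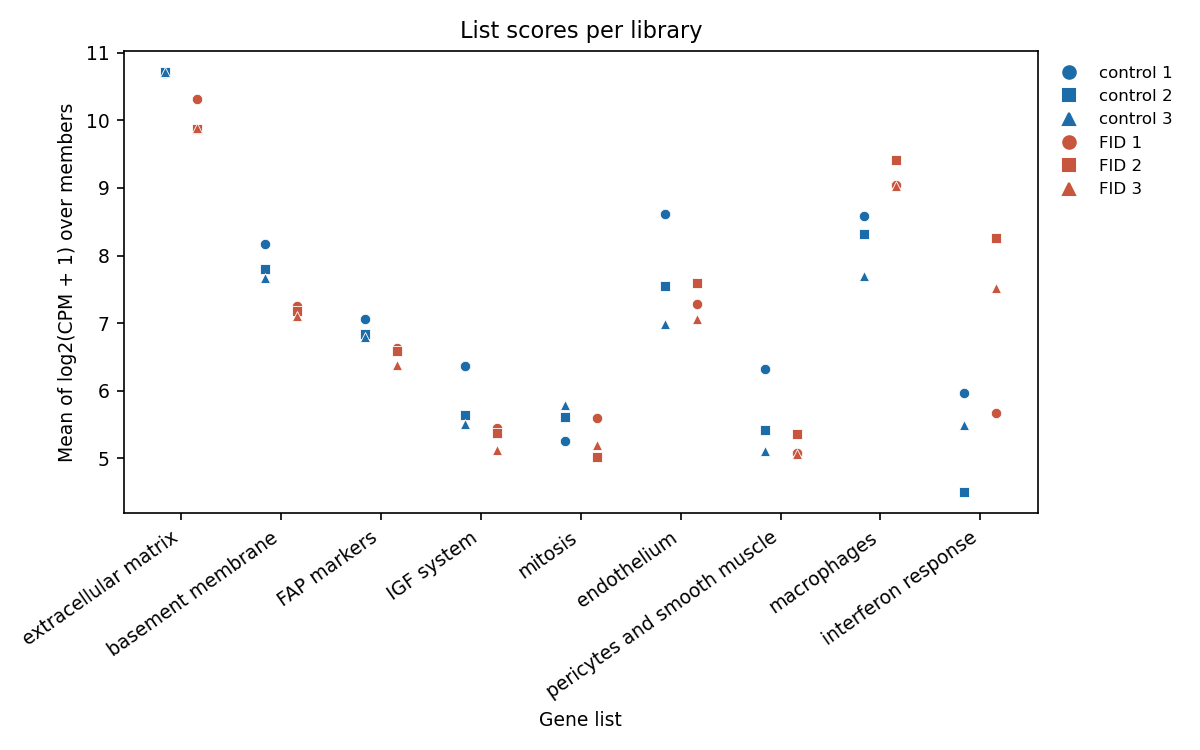
Mean of log2(CPM + 1) over the members of 9 gene lists, with 1 point per library (blue control, red FID, symbols for the replicate number). The macrophage scores of the FID libraries (9.02 to 9.42) lie above those of control (7.70 to 8.58), whereas the interferon score of FID 1 (5.67) lies within the control range.

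Vessel-associated genes were lower in FID, and this rested on control 1. The endothelium list fell with a median of -0.60 (camera adjusted p 0.0276; adjusted p = 0.755 with an estimated correlation), but its median was 0.03 without control 1 (camera adjusted p 0.753). Pericyte and smooth muscle genes fell with a median of -0.48 (camera adjusted p 0.0138; adjusted p = 0.691 with an estimated correlation) and had 0.04 without control 1 (camera adjusted p 0.189). Without FID 1 both missed the threshold with similar medians, -0.53 for endothelium (camera adjusted p 0.0789) and -0.43 for pericytes (camera adjusted p 0.0770), as did endothelium without FID 3, at -0.43 (camera adjusted p 0.115). The endothelial marker Pecam1 stood at 954 CPM in control 1 and at 310 to 476 CPM in the other libraries. Cspg4, a pericyte proteoglycan, measured 47.4 ± 11.7 against 28.7 ± 2.92 CPM.

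Muscle lists did not pass. Satellite cell and myoblast genes had a median of -0.31 (camera adjusted p 0.498), and Notch3, a receptor also made by vessel walls, measured 159 ± 55.3 against 84.4 ± 14.4 CPM. Embryonic and neonatal muscle genes had a median of -0.23 and mature myofibre genes of -0.31 (camera adjusted p 0.822 and 0.864), and camera gave both the direction up, against the sign of their medians. These 3 medians were 0.38, 0.82 and 0.74 without control 1 and 0.035, 0.024 and 0.037 without FID 3, so their sign rested on those libraries. Tenocyte genes had a median of -0.97 (camera adjusted p 0.167), which was -0.14 without control 1 and -1.02 without control 2, where the list passed (camera adjusted p 0.0163). Among them was the lubricin gene Prg4 at 367 ± 96.7 against 119 ± 74.5 CPM. Adipocyte genes had a median of -0.01 and a mean of 0.03 (camera adjusted p 0.520), and Schwann cell genes a median of 0.07 and a mean of -0.13 (camera adjusted p 0.822), and both medians took either sign with 1 library left out (-0.051 to 0.24 and -0.072 to 0.18). Lists for T and NK cells, B cells, mast cells, erythrocytes and skin keratinocytes had 4, 3, 1, 3 and 3 members left after filtering and were not tested on the filtered genes. With no filter on low counts they were tested, and the mast cell list passed upward with a median of 2.61 over 9 members (camera adjusted p 0.00948), whereas the others did not pass (camera adjusted p 0.114 to 0.489). The mast cell members left out by the filter had few reads and were mostly highest in FID 2. Cpa3, Cma1, Mcpt4 and Tpsb2 stood at 2.94 to 3.88 CPM in FID 2 and at most 1.19 CPM in any other library. The list score was 1.36 in FID 2 against 0.731 and 0.732 in FID 1 and 3.

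Transcripts of oxidative metabolism were higher on average in the libraries labelled FID. Mitochondrially encoded genes rose with a median of 0.48, all 10 tested members being above 0 (camera adjusted p 0.00120; adjusted p = 0.636 with an estimated correlation). Their median was 0.28 without FID 2 and 0.73 without control 3. They took 1.34 ± 0.251% of gene counts in control and 2.26 ± 0.667% in FID (SD, n = 3 each), and mt-Co1 had a log2 fold change of 0.72 (SE 0.26). The share in FID 1 (1.625%) lay below that in control 3 (1.629%), and 0 of the 10 members separated the groups without overlap. Nuclear genes of oxidative phosphorylation rose with a median of 0.14, 26 of 27 being above 0 (camera adjusted p 0.00203; adjusted p = 0.636 with an estimated correlation), and Sdhb had 0.38 (SE 0.12). Glycolysis genes had a median of 0.18 (camera adjusted p 0.178), which was 0.096 without control 1 and 0.22 without control 2, where the list passed (camera adjusted p 0.0462), whereas Hk2, the hexokinase of muscle and activated cells, measured 228 ± 69.2 against 116 ± 29.2 CPM.

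Mitotic genes were slightly lower in FID. The list fell with a median of -0.23, with 24 of 25 members below 0 (camera adjusted p 6.46e-04; adjusted p = 0.701 with an estimated correlation), but it had -0.09 without control 3 (camera adjusted p 0.112), -0.12 without FID 2 and -0.38 without FID 1. Mki67, a marker of cycling cells, measured 98.8 ± 24.2 against 44.3 ± 23.9 CPM, Foxm1 43.9 ± 3.24 against 28.2 ± 5.49 CPM and the kinetochore motor gene Cenpe 42.3 ± 3.36 against 25.2 ± 8.75 CPM. DNA replication genes had a median of -0.15 (camera adjusted p 0.119), and passed at -0.39 without control 1 (camera adjusted p 2.88e-05) and at -0.30 without FID 1 (camera adjusted p 0.00668), but had -0.0063 without control 3 (camera adjusted p 0.995). Ribosome biogenesis genes had a median of -0.01 (camera adjusted p 0.309). Immediate early and heat shock genes fell with a median of -0.31 (camera adjusted p 0.0276; adjusted p = 0.519 with an estimated correlation). That call was lost without control 3, at a larger median of -0.42 (camera adjusted p 0.112), and without FID 3, at -0.17 (camera adjusted p 0.0866), and the median was -0.20 without control 1 and -0.50 without FID 1. Fosb measured 1838 ± 164 against 1271 ± 124 CPM and Nr4a1 928 ± 19.8 against 612 ± 121 CPM.

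Complement genes moved both ways, with a median of -0.25 that did not pass (camera adjusted p 0.229) and ranged from -0.48 without FID 2 to 0.028 without control 1. C3, the central complement component, measured 419 ± 61.5 CPM in control and 172 ± 42.4 CPM in FID, and C7 4.40 ± 1.98 against 0.432 ± 0.284 CPM. The C7 values of FID 1 and FID 2 (0.225 and 0.315 CPM) did not exceed their floors of 0.338 and 0.315 CPM. C3ar1, a receptor for a fragment of C3, measured 121 ± 39.8 against 292 ± 49.4 CPM. Fry's mixed test, which counts change in either direction, gave an adjusted p of 0.0188 for this list and of 0.0477 for each of the lists of extracellular matrix, basement membrane and matrix proteases. Genes for ligands made by FAPs had a median of -0.21 (camera adjusted p 0.178), which ranged from -0.38 without control 1 to 0.012 without control 3. In that list were Sfrp1, a secreted Wnt inhibitor, at 327 ± 23.0 against 177 ± 17.5 CPM and the chemokine gene Ccl11 at 65.3 ± 10.1 against 168 ± 71.5 CPM. The FoxO and atrophy programme had a median of -0.32 (camera adjusted p 0.489), or 0.10 without control 1.

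**Figure D3:**
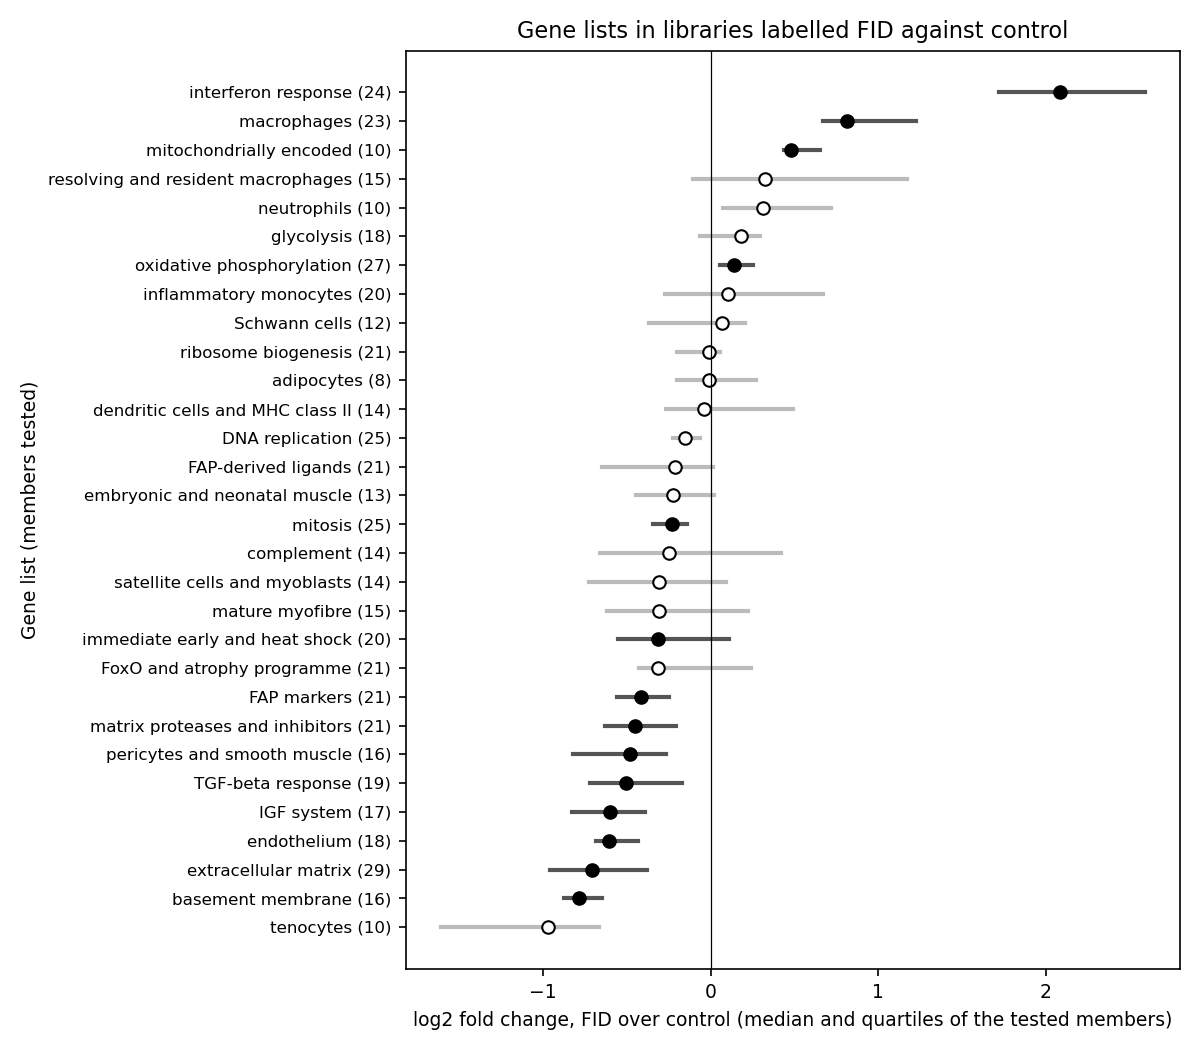
Median (points) and quartiles (bars) of the log2 fold changes of the tested members of 30 gene lists, FID over control, with the number of tested members in parentheses. Filled points mark the 14 lists that passed camera with its preset correlation, from interferon response (2.08) down to basement membrane (-0.78).

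In all, 14 of 30 lists passed camera with the preset correlation, 4 up and 10 down, whereas 0 passed with an estimated correlation or in fry's direction test, whose smallest adjusted p was 0.0667, and 4 passed fry's mixed test. The other 9 ways of splitting these 6 libraries into 3 and 3 gave between 5 and 19 lists with the preset correlation.

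Sex-linked transcripts differed within both groups, and control 3 stood apart from the other libraries. Xist, the X-inactivation RNA of female cells, stood at 51.6, 30.4 and 25.8 CPM in control 1, FID 1 and FID 2, where the sum over 4 Y-linked genes was 0. Y-linked transcripts summed to 122 CPM in control 2 and 163 CPM in FID 3, with Xist at 0.507 and 0 CPM. Control 3 held both, with Xist at 13.7 CPM and Y-linked transcripts at 90.9 CPM. Ifi202b, an interferon-inducible gene with close relatives nearby, had no count in control 3, 75.7 and 121 CPM in control 1 and 2, and 230, 246 and 260 CPM in FID 1, 2 and 3 (edgeR adjusted p 0.431). Hal, which encodes histidine ammonia-lyase, stood at 0.879 CPM in control 3, at 127 and 122 CPM in control 1 and 2, and at 241, 409 and 315 CPM in FID 1, 2 and 3 (edgeR adjusted p 0.379). Both genes thus separated the groups without overlap but did not pass the test.

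**Figure D4:**
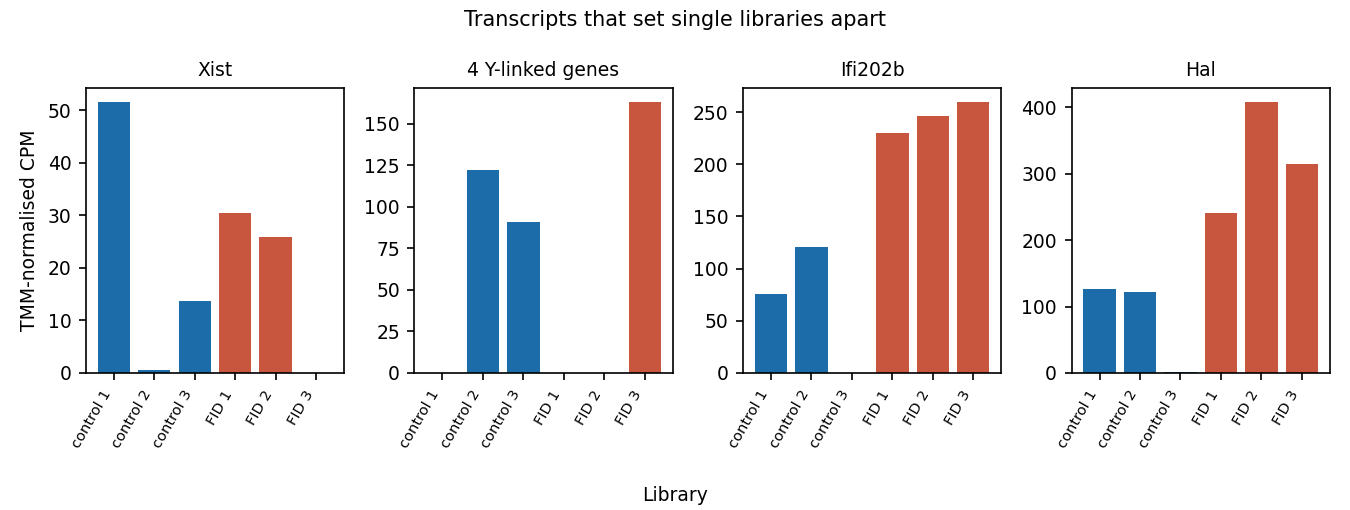
TMM-normalised CPM of Xist, of the sum of 4 Y-linked genes, of Ifi202b and of Hal, with 1 bar per library (blue control, red FID). Control 3 holds both Xist (13.7 CPM) and Y-linked transcripts (90.9 CPM) and has 0 CPM of Ifi202b.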

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

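The alternatives Y-linked transcripts as a covariate and robust shrinkage in edgeR were chosen after seeing the data. The count of genes past the adjusted threshold was 0 in edgeR and stayed 0 under other scaling, a stricter filter, limma-voom, both sex covariates, robust shrinkage and with mitochondrial or myofibre genes left out. It was 269 with no filter on low counts, 760 in DESeq2 and 1531 in limma-voom with sample weights, and 0 to 359 when 1 library was left out (359 without FID 1, 3 without control 1). DESeq2 and limma-voom with sample weights shared 704 genes. The cause was not tested. The log2 fold change of Igf1 was 0.010 with library totals only, 0.015 with no filter, 0.060 in limma-voom, 0.38 with sample weights and 0.069 with Xist as a covariate, and -0.27 to 0.25 when 1 library was left out, and it passed the threshold in none of these.

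The number of lists past the threshold was 0 in camera with an estimated correlation and 0 in fry's direction test, with 4 in fry's mixed test. With the preset correlation it ranged from 12 to 19, and from 12 to 18 when 1 library was left out. With Y-linked transcripts as a covariate, 5 lists that had not passed were called down, at -0.63 for embryonic and neonatal muscle, -0.45 for mature myofibre, -0.56 for satellite cells and myoblasts, -1.13 for tenocytes and -0.39 for complement. Of 21 alternatives, 6 called tenocytes (DESeq2, camera adjusted p 0.00618, among them), 6 resolving and resident macrophages (DESeq2, 0.0202, among them), 3 DNA replication (sample weights, -0.31, among them) and 2 neutrophils. Without control 1, dendritic cells and MHC class II (0.35), FAP-derived ligands (-0.38) and ribosome biogenesis (-0.14, with up to 0.044 when another library was left out) were called, and without control 2 glycolysis (0.22). The endothelium median ranged from -0.91 to 0.034 when 1 library was left out, the latter without control 1. With sample weights, oxidative phosphorylation (camera adjusted p 0.0501), endothelium (0.0884) and pericytes (0.0530) missed the threshold. The cause was not tested. The fixed rule gives 115 genes beside Igf1, and 108 kept their direction under each alternative that tested them. The other 7 were Ncam1, Hbb-bs and Hba-a1, which turned without control 1, Myh3, which turned without control 1 and with sample weights, and Kdm5d, Eif2s3y and Ddx3y, which turned with other libraries left out. Of the 115, 56 passed in DESeq2, 63 with sample weights, 34 with no filter, 32 without FID 1, 1 without control 1 and 0 under the other 15 of 20 alternatives. With no filter, the mast cell list was tested and called up (median 2.61 over 9 members, camera adjusted p 0.00948), on members that mostly had few reads and were highest in FID 2. Its 1 member in the filtered set, Kit, had a log2 fold change of -0.97.

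With the replicate number as a block, edgeR called 0 genes, Igf1 had a log2 fold change of 0.044 and 16 lists passed. The deviations of libraries with the same number correlated at 0.01, -0.30 and 0.32 across genes, so the numbers were not taken to pair the samples. Control 1, at 5201853 counts, has the highest floor, 0.593 CPM.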

Other observations

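Of the tests in this part, all except the counts over other splits of the libraries were chosen after the results they bear on were seen.

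The 9 other splits of the 6 libraries into 3 and 3 are too few, with the real one, for a share under 0.05. The labelled split gave 0 genes in edgeR (highest other 3, and all 10 splits gave as many or more), 2449 genes with an unadjusted p under 0.05 (highest other 1288; 1 split as large) and 760 genes in DESeq2 (highest other 224; 1 split as large). For gene lists it gave 14 (highest other 19), and 6 splits gave as many or more.

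Macrophage transcripts were higher and matrix transcripts lower in the libraries labelled FID, with a gap of 1.52 between the medians of the lists. Unequal sex is argued against as the whole cause, since the gap was 1.46 with Y-linked transcripts as a covariate. A lower share of matrix-producing cells alone would raise macrophage and endothelial markers alike, if the ratio of the other cells stayed the same. The macrophage score minus the endothelium score was 1.00 higher in the lowest FID library than in the highest control library (exact two-sided permutation p 0.10, n = 3 each). The lists were compared after macrophage genes were seen to rise and endothelial genes to fall, so this separation does not decide the question. A larger share of macrophages alone would lower matrix genes and FAP markers by the same factor; the matrix score minus the FAP marker score differed by -0.32 between the groups (exact two-sided permutation p 0.200, the smallest possible being 0.10, n = 3 each), so this cannot be told apart from lower matrix expression per cell. An effect of the Igf1 deletion, which the design names, stays open and untested, as do changes within macrophages and, if the RNA came from isolated cells, the purity of the preparation.

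Igf1 was alike in both groups although the design names its deletion. An exchange of the labels of 1 control and 1 FID library is argued against by the counts of genes. Each of the 9 splits that would undo it gave fewer genes with an unadjusted p under 0.05 (highest 1288) than the labelled split (2449). Distances between libraries were mixed. By chi-square per degree of freedom, no control library lay closer to FID 2 or FID 3 than to the other control libraries. By that measure control 3 lay closer to FID 1 (34.4) than to control 1 (46.0). By Spearman correlation, control 3 lay closer to FID 3 (0.962) and FID 2 (0.948) than to control 1 (0.944). A single wrong label on FID 1 was not excluded, since it lay closer to control 2 (chi-square per degree of freedom 24.4) than to FID 2 (42.8) or FID 3 (28.7), and by lists called the exchanged splits reached 19 against 14. Macrophages as the only source of Igf1 at a constant output would have carried Igf1 up with their list, which lay 0.83 above it on the log2 scale, more than 2 SE of Igf1 (0.56). That comparison bears on macrophages as the only source. Whether they supplied part of the Igf1 reads, in unequal amounts between the groups, was not tested and stays open. Reads from exons outside the deleted part may hold the whole-gene value at -0.010, and this cannot be told apart here without counts per exon.

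Control 3 lacked Ifi202b and Hal and held both Xist and Y-linked transcripts, and 5 genes were at under 0.1 of the lowest other library in it, against at most 1 in any other. Too few reads are argued against, since the lowest other library predicts 765 reads of Ifi202b in control 3. RNA from another library of this series is argued against as the source of both sex markers, since the Xist share would bring 20.1 CPM of Ifi202b and none was counted. A pool of animals of both sexes may account for the sex markers, since Xist and Y-linked transcripts, each relative to the highest other library, summed to 0.82. A different strain background of its animals remains a hypothesis that was not tested, and Hal lies 5.55 Mb from Igf1 on chromosome 10. Ifi202b and Hal were also higher in every FID library than in control 1 and control 2. Whether the background differs between the groups was not tested either.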
